A study of Mus musculus with 2 samples.

How the data were processed

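The series holds RNA sequencing of mouse eyeballs from C57BL/6 animals in a model of oxygen-induced retinopathy (OIR). In this model young pups are kept in high oxygen, which stops the growth of retinal vessels and closes some of them, and are then returned to room air, where the retina that lacks vessels becomes hypoxic and new vessels sprout. Per the labels, pups entered the hyperoxia chamber at day 7, stayed for 5 days and then lived in room air until the eyes were taken at day 17. The labels give 1 control sample and 1 OIR sample, and do not give the number of eyes or animals in each, their sex, or a separate collection day for the control. The labels' protocol names total RNA as input and the NEBNext Ultra RNA kit for the libraries.

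Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the mouse build mm10 were used. The order and settings of these tools, the annotation release and whether the counting used strand are not given in the sources used here. One deposited table covers both libraries. Per the file headers it holds read counts, taken here as raw, and FPKM values per gene for each library. It also holds counts the authors divided by 1 factor per library, a scaled signal used here only to read off those factors. The authors' deposited table further gives a log2 fold change and p-values of the OIR library against the control library, and a gene length. The tool behind that comparison is not given in the sources used here. Those p-values compare 1 library with 1 library and say nothing on the spread between animals. For all 22320 genes with reads in both libraries, count and FPKM gave the same gene length in both libraries within 0.1%, so the ratio of FPKM values equals the ratio of read shares. This implied length equalled the deposited gene length within 1 base for only 8939 of these genes. Transcript length below means the implied length.

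The table lists 47644 genes after 5 lines of broken-off annotation text were dropped. Symbols came from the table for 22528 genes and from GENCODE M21, matched by Ensembl identifier, for 24246, and 870 had none. Among the symbols, 27 appear in the form of calendar dates. Of the genes matched to GENCODE M21, an annotation of the same build, 99.95% overlapped its span there. Coordinates are the table's own, on mm10. Gene types are those of GENCODE M21. Spans of some named genes overlap those of other genes, Angpt2, Esm1, Plvap, Epo, Gfap, Fgf2, Hk1, Cx3cr1, Irf7, Pmel and Gad1 among them. Their reads are uncertain to the extent that the authors' counting could not separate the overlapping parts.

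Expression was compared as the difference of log2(FPKM + 1), OIR minus control, which understates the change of genes at low FPKM. Genes with an FPKM of at least 1 in either library were used, 15883 in all, and these are called tested genes although no statistical test was made. With 1 library per group there is no replicate check of any difference, and no p-value or standard error was computed. A gene is called at least 2-fold higher or lower by size alone, where the difference is at least 1 or at most -1. Beside a ratio of read shares stands its exact conditional 95% interval (Clopper-Pearson). These intervals, and the exact binomial intervals of shares, cover counting error only: reads without molecular identifiers are not independent molecules, and animals differ.

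Before the data were examined, 53 lists of genes were fixed: markers of the cell types of the eye and of tissues that an eyeball sample can hold, pathways, technical sets and a 16-gene retinopathy panel. For each list with at least 4 tested members, the median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 50 bins. A list is called above or below where it lies outside the central 95% of these, as a description of the 2 libraries. The lists overlap in part. The rule for naming genes was also fixed then: every measured panel gene, the 8 highest and 8 lowest differences among genes with a symbol and an FPKM of at least 5 in either library, and, for each list outside its random range, the 3 members farthest in the direction of its median. Some genes that this rule takes are not reported here. Any other gene named was chosen after its values were seen, which is said where it is named.

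The alternatives fixed at that time were pseudocounts of 0.1 and 0.01, no filter, an FPKM filter of 5, centring on the median of all tested genes, rescaling to TPM with and without lens, muscle, erythrocyte and mitochondrial genes, protein-coding genes alone, CPM from the read counts, thresholds of 1.5-fold and 4-fold, the mean of a list in place of its median, and leaving out genes at 0 in 1 library. The authors' scaling factors and centring within 20 bins of transcript length were added after the data were seen. The procedure was tested on simulated Poisson counts drawn from the mean read shares and the library sizes of the control and OIR libraries, with 200 genes changed, over 15588 genes. In each of the groups of 50 genes raised 3-fold, lowered 3-fold, raised 6-fold and lowered 6-fold, 100% were called, and 0.898% of 15375 unchanged genes passed the rule of size. A simulated list of 13 genes raised 1.5-fold lay at percentile 100, and 8% of 50 unchanged lists fell outside the central range. The changed genes and the raised list were drawn from genes with an FPKM of at least 5 in both libraries. Recovery of genes at lower FPKM was not tested, and Poisson counts carry no spread between animals. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.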

Results

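RNA from mouse eyeballs was sequenced from 1 control sample and 1 sample of the oxygen-induced retinopathy model at day 17, after 5 days of hyperoxia that began at day 7. By the stated purpose of the series, the comparison addresses what goes with long-lasting visual dysfunction in this model. The control library held 15741235 reads assigned to genes and the OIR library 20378793, and 23604 and 25307 genes had at least 1 read. For a transcript of median length, 3 reads correspond to an FPKM of 0.105 in the control and 0.0814 in OIR. No difference below has a replicate check, because each group is 1 library, and the intervals given cover counting error only.

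The OIR library carried higher levels of hypoxia, vessel growth and glial reactivity genes and lower median levels of inner retinal neuron genes, while the median of the rod list lay near 0. Genes of tissues outside the neural retina also differed in these whole-eyeball samples: corneal and conjunctival epithelium and erythrocyte genes had median differences of 1.21 and 1.22, lens genes -0.47, and the share of rRNA reads was 19.4-fold higher in OIR. In the panel of 16 genes fixed for retinopathy, 9 were at least 2-fold higher in OIR, none was at least 2-fold lower, and the median difference was 1.34 on the log2 scale, above the 95% range of matched random lists (-0.12 to 0.26). Vegfa, the main growth factor for new vessels (ENSMUSG00000023951, chromosome 17, 46016993 to 46032377), stood at 331 FPKM in OIR and 111 in the control, a read-share ratio of 2.99 (95% interval 2.86 to 3.12). Apln, which encodes the apelin peptide of sprouting endothelium (ENSMUSG00000037010, chromosome X, 48025146 to 48034853), had 1377 reads in OIR and 98 in the control, a ratio of 10.9 (8.84 to 13.5). Adm, the adrenomedullin gene (chromosome 7, 110627661 to 110629820), had a ratio of 15.7 (9.37 to 28.4) from 305 and 15 reads.

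Other panel genes linked to sprouting vessels were also higher. Esm1, a tip cell gene, had a ratio of 9.27 (5.65 to 16.2), Angpt2, an antagonist of the Tie2 receptor that loosens vessels, 3.86 (3.08 to 4.89), and Igfbp3 3.23 (2.80 to 3.74). Pgf and Plvap were less than 2-fold apart, with ratios of 1.87 (1.44 to 2.45) and 1.63 (1.36 to 1.97). Epo had 21 reads in OIR and 1 in the control, and its ratio of 16.2 has an interval of 2.61 to 671; its span in the table also overlaps other genes, Gnb2 among them. The genes of the hypoxia-inducible factors themselves differed little: Hif1a stood at 135 and 136 FPKM, with a ratio of 0.998 (0.962 to 1.04), and Epas1 had a ratio of 1.31 (1.24 to 1.37). The glucose transporter gene Slc2a1 had a ratio of 1.16 (1.12 to 1.20). For scale, the median tested gene stood 0.11 higher in OIR on the log2 scale. The authors' scaling factors shift every log2 ratio of read shares by -0.14, and differences of log2(FPKM + 1) by less at low FPKM.

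**Figure D1:**
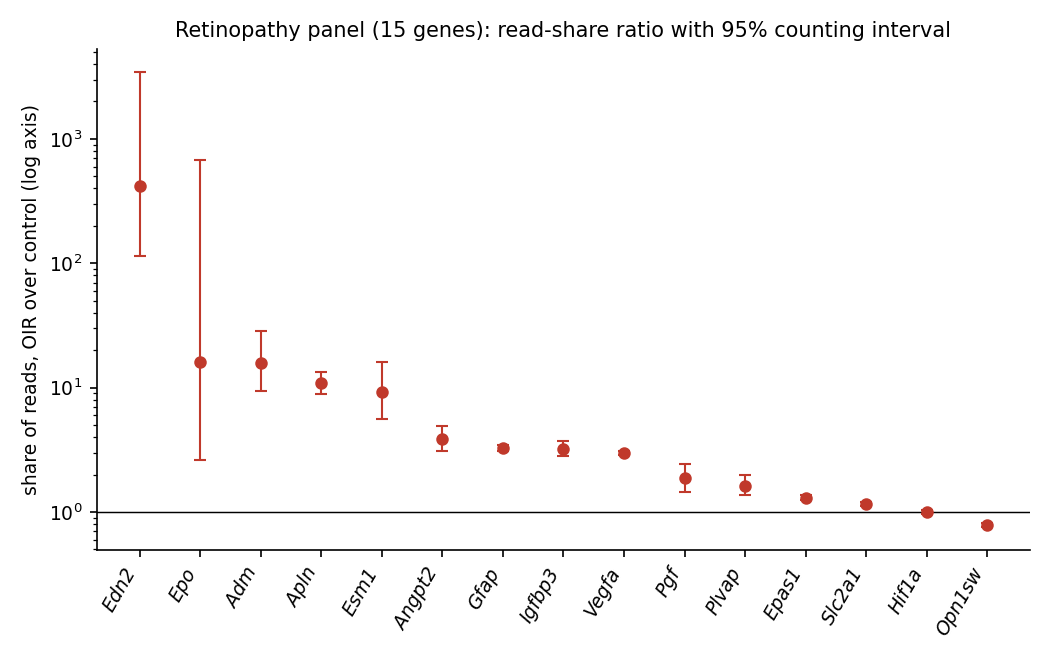
Ratio of the share of reads, OIR over control, for 15 of the 16 genes of the retinopathy panel, on a log axis. Points are the ratios and bars their exact 95% counting intervals, with 1 library per group. Edn2 has the highest ratio, with 2 reads in the control, and Opn1sw the lowest, at 0.789.

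The hypoxia-induced list had a median difference of 0.53 over 24 genes, above its random range (-0.09 to 0.20). In it 22 genes lay above 0 and 5 were at least 2-fold higher, led by Adm, Stc2 with a ratio of 4.02 (3.10 to 5.26) and Vegfa. Glycolysis enzymes had a median of 0.32 over 15 genes, outside -0.30 to 0.11. Pfkp, a phosphofructokinase that commits glucose to glycolysis, stood at 551 FPKM in OIR and 198 in the control. The hexokinase gene Hk1 and the phosphofructokinase gene Pfkl had ratios of 1.71 (1.66 to 1.76) and 1.70 (1.64 to 1.77).

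Vascular lists lay above their random ranges, with the exception of the blood-retina barrier list. Of the 18 endothelial tip cell genes 9 were at least 2-fold higher, with a median difference of 1.14. The panel holds 6 of these 18, and the other 12 had a median of 0.87. Angiogenic growth factors and receptors had a median of 0.67 over 22 genes, and the 17 of them outside the panel had 0.48. Endothelial markers had a median of 0.69 over 15 genes and pericyte and smooth muscle markers 0.52 over 12. All 15 endothelial markers lay above 0, but only 1 of them, Ecscr, was at least 2-fold higher on the log2(FPKM + 1) scale, which understates the ratio at low FPKM. Pecam1 and Eng, found across endothelium, had ratios of 2.09 (1.82 to 2.40) and 2.02 (1.81 to 2.26). Cspg4, which encodes the NG2 proteoglycan of pericytes, had a ratio of 3.28 (2.64 to 4.10), Notch3 2.32 (2.07 to 2.60) and Rgs5 1.69 (1.61 to 1.78). Of the 12 genes of the pericyte list 8 lay above 0 and 4 below, and only 1, Cspg4, was at least 2-fold higher. With the mean in place of the median the pericyte list lay inside its random range. The 12 blood-retina barrier genes had a median of 0.18, within their range of -0.12 to 0.31. Erythrocyte genes stood beside these vessel lists with a median of 1.22 over 7 genes, and took 0.104% of reads in OIR (0.103 to 0.106) and 0.0439% in the control (0.0429 to 0.0450). Alas2, the first enzyme of heme synthesis in red cells, had a ratio of 3.30 (2.53 to 4.36), and the globin genes Hbb-bs and Hbb-bt, near-identical copies whose reads are uncertain between them, 3.36 (3.21 to 3.51) and 2.66 (2.36 to 3.01).

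Reactive gliosis genes had the highest median of all lists, 1.63 over 17 genes, and 12 of these were at least 2-fold higher, beside the corneal epithelium list at 1.21 and the erythrocyte list at 1.22. Other lists also hold 8 of these 17 genes, and the 15 outside the panel had a median of 1.58. Edn2, the endothelin 2 gene (ENSMUSG00000028635, chromosome 4, 120161206 to 120167360), had 1081 reads in OIR and 2 in the control, or 36.3 and 0.0869 FPKM, with a ratio of 418 (115 to 3452). Bcl3, a regulator of NF-kappaB, had 417 and 12 reads, a ratio of 26.8 (15.2 to 52.4). Fgf2 (chromosome 3, 37348346 to 37410108) had a ratio of 12.2 (10.2 to 14.7). Its span overlaps genes on the other strand, among them Fgf2os, and whether the counting used strand is not given in the sources used here. Gfap, the intermediate filament of astrocytes and stressed Müller glia (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), stood at 144 FPKM in OIR and 43.9 in the control, a ratio of 3.28 (3.08 to 3.48).

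Markers of Müller glia, the main supporting cells of the retina, had a median difference of -0.28 over 12 genes, below -0.22 to 0.21. Glul, the glutamine synthetase that recycles glutamate, stood at 1017 FPKM in OIR and 1753 in the control, a ratio of 0.580 (0.569 to 0.591). Abca8a and Rlbp1, the latter a carrier of visual cycle retinoids, had ratios of 0.677 (0.630 to 0.728) and 0.698 (0.672 to 0.724). The members did not go 1 way: 4 lay above 0, and Sox9 and Crym, chosen after their values were seen, had differences of 1.12 and 1.48. The mean over the list was -0.02, inside its random range. Astrocyte and oligodendrocyte markers had a median of 0.13 over 13 genes, within their range.

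Lists of inner retinal neuron genes had lower medians in OIR, and none of their members was at least 2-fold lower on the log2(FPKM + 1) scale. The lens list was lower beside them, at -0.47. Retinal ganglion cell markers had a median of -0.45 over 16 genes, 15 of them below 0, outside -0.07 to 0.25. Thy1, a surface protein of ganglion cells (chromosome 9, 44043384 to 44048579), stood at 65.2 FPKM in OIR and 105 in the control, a ratio of 0.621 (0.588 to 0.656). Sncg and Slc17a6, a synuclein and a vesicular glutamate transporter, had ratios of 0.598 (0.547 to 0.653) and 0.609 (0.546 to 0.678). GABA and glycine receptor genes had a median of -0.44 over 15 genes, 14 below 0, with Glra2 at 0.510 (0.414 to 0.625) and Gabrr2 at 0.665 (0.587 to 0.753). Bipolar cell markers had a median of -0.19 over 17 genes, amacrine markers -0.15 over 18, horizontal cell markers -0.20 over 6 and glutamate receptor genes -0.09 over 17, each below its random range, with 5 bipolar, 2 amacrine, 1 horizontal cell and 5 glutamate receptor genes above 0. In the bipolar list Scgn had a ratio of 0.574 (0.513 to 0.641), Cabp5 0.629 (0.573 to 0.690) and Pcp2 0.681 (0.619 to 0.749). Among amacrine markers the neuropeptide gene Vip had 0.445 (0.307 to 0.640), Calb2 0.609 (0.582 to 0.637) and Gad1, which makes GABA, 0.633 (0.598 to 0.671). Calb1 of horizontal cells had 0.609 (0.553 to 0.671), while Lhx1, at 0.804, had an interval that included 1 (0.603 to 1.07). With an FPKM filter of 5 the horizontal and amacrine lists lay inside their random ranges. The glutamate receptor genes Grik1, Gria4 and Grm8 had ratios of 0.677 (0.615 to 0.745), 0.770 (0.709 to 0.837) and 0.752 (0.632 to 0.895).

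Rod and cone lists had medians within their random ranges. Rod markers had a median of 0.03 over 17 genes and took 3.62% of reads in OIR (3.61 to 3.63) and 3.58% in the control (3.57 to 3.59). Cone markers had a median of 0.09 over 13 genes, with single differences from -0.48 to 1.12, the highest that of Gnb3, chosen after its values were seen, and Opn1sw, the short-wave cone opsin, had a ratio of 0.789 (0.755 to 0.824). Guca1a, which encodes a guanylate cyclase activator of photoreceptors and was chosen after its values were seen, stood at 83.1 FPKM in OIR and 190 in the control, a difference of -1.18. Ribbon synapse genes, at 0.03 over 18, and retinal dopamine genes, at -0.10 over 9, were within range. Visual cycle genes had a median of 0.29 over 14 genes, above -0.15 to 0.22, with Rbp3 and Rdh10 at 1.63 (1.61 to 1.66) and 1.52 (1.42 to 1.63). The mean of that list was inside its random range. Retinal pigment epithelium markers had a median of -0.00 over 14 genes.

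**Figure D2:**
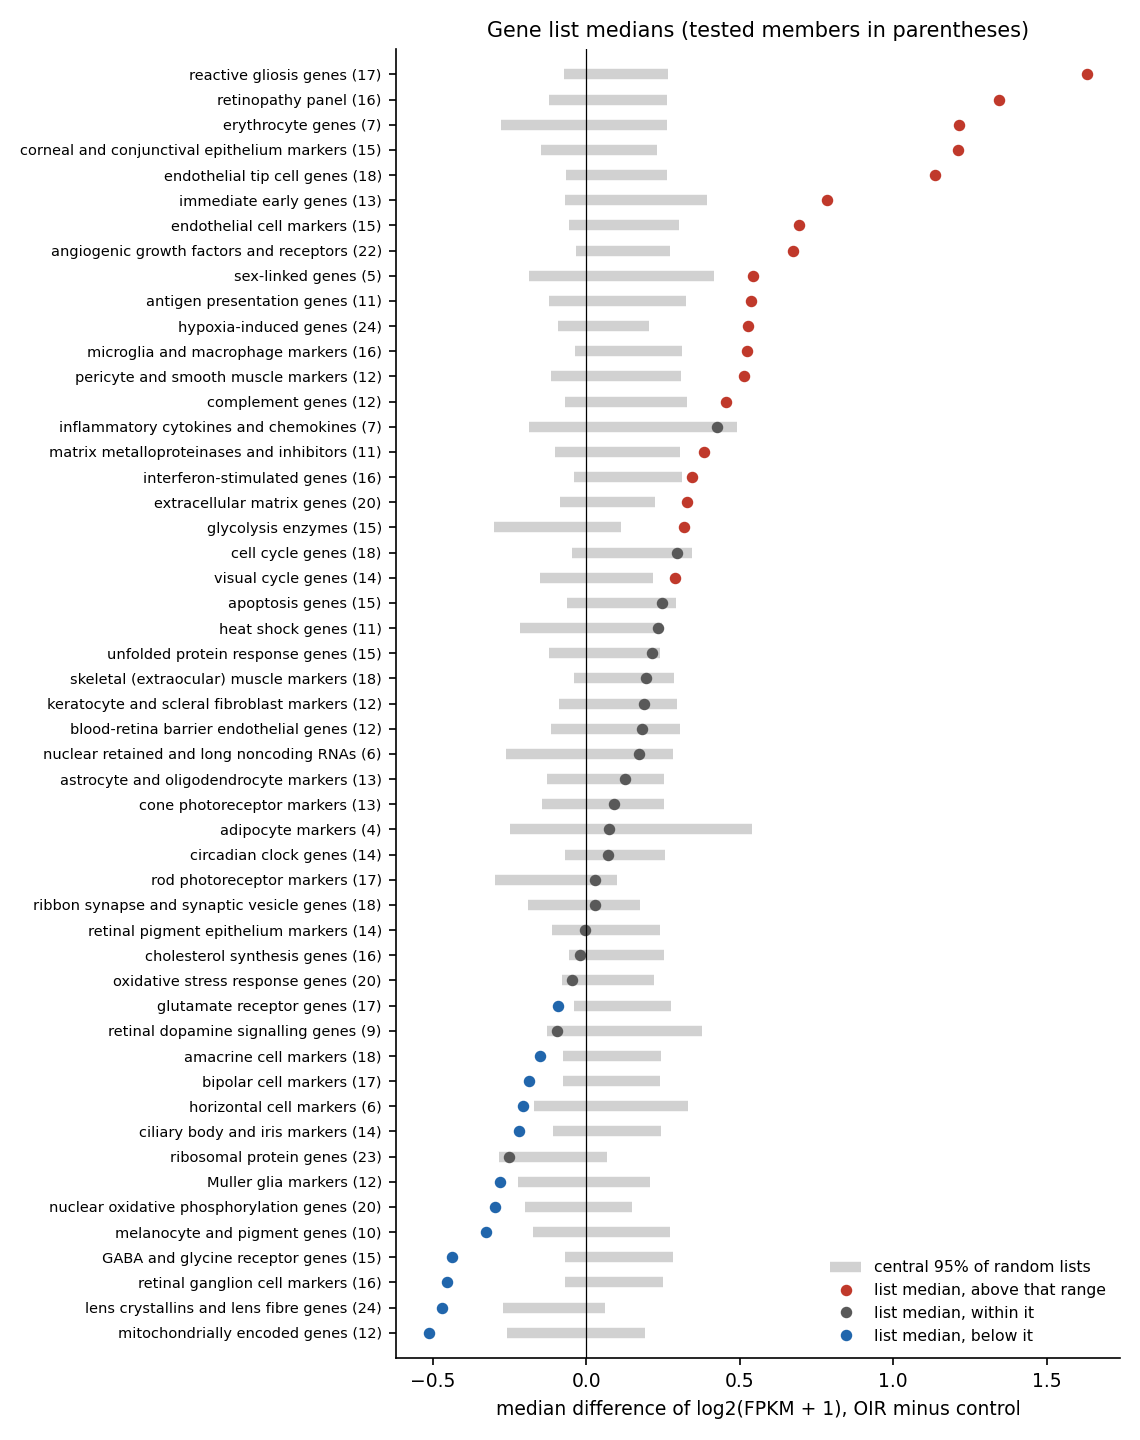
Median difference of log2(FPKM + 1), OIR minus control, for each of the 51 ranked gene lists, with the number of tested members in parentheses. Grey bars are the central 95% of 10000 random lists of the same size matched on mean expression. In all 19 lists lay above, 12 below and 20 within. The reactive gliosis list (1.63) and the mitochondrially encoded list (-0.51), which holds no rRNA genes, mark the ends.

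Immune genes were moderately higher in OIR. Microglia and macrophage markers had a median of 0.52 over 16 genes, 15 above 0 and none at least 2-fold higher, with Cd68 at a ratio of 2.18 (1.57 to 3.06), Cx3cr1 at 2.37 (1.85 to 3.06) and C1qb at 1.93 (1.59 to 2.36). Complement genes had a median of 0.45 over 12, with C4b at 3.63 (3.17 to 4.17) and C3 at 4.34 (2.71 to 7.27). Antigen presentation genes had 0.54 over 11, led by the class II gene H2-Ab1 at 5.14 (3.53 to 7.71), then H2-D1 at 2.11 (1.94 to 2.30) and Tap2 at 2.11 (1.55 to 2.92). The other class II genes of the list, chosen after their values were seen, did not follow H2-Ab1: H2-Aa had a ratio of 1.27 (0.672 to 2.48) and H2-Eb1 0.662 (0.483 to 0.906). Interferon-stimulated genes had 0.35 over 16, with Irf7 at 2.86 (2.31 to 3.56), Oasl2 at 1.80 (1.48 to 2.21) and Irf9 at 1.77 (1.52 to 2.07), and lay inside their range with an FPKM filter of 5. Cytokines and chemokines had a median of 0.43 over 7 genes, within -0.19 to 0.49. Of the neutrophil and lymphocyte markers only 2 reached an FPKM of 1, with a median of -0.15, too few to rank.

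Immediate early genes, the transcription factors induced first after a stimulus, had a median of 0.79 over 13 genes. All lay above 0, and 4 of them were at least 2-fold higher. Atf3 had a ratio of 7.24 (4.93 to 11.0), Nr4a1 3.96 (3.42 to 4.60) and Junb 3.69 (3.18 to 4.29). Extracellular matrix genes had a median of 0.33 over 20, beside the corneal epithelium list at 1.21 and the keratocyte and scleral fibroblast list at 0.19, with fibronectin, Fn1, at 84.6 FPKM in OIR and 17.8 in the control and Loxl2 and Col5a2 at ratios of 2.32 (2.02 to 2.66) and 1.89 (1.62 to 2.21). Matrix metalloproteinases and inhibitors had 0.38 over 11, with Timp1 at 2.78 (1.80 to 4.42) and Plat at 1.98 (1.74 to 2.27). Cell cycle genes (0.30), apoptosis genes (0.25), heat shock genes (0.23), unfolded protein response genes (0.21), circadian clock genes (0.07), cholesterol synthesis genes (-0.02) and oxidative stress response genes (-0.04) had medians within their random ranges.

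Respiratory chain genes were lower in OIR. The mitochondrially encoded list had a median of -0.51 over 12 genes, all below 0, and took 1.435% of reads in OIR (1.430 to 1.440) against 1.984% in the control (1.978 to 1.991). In it mt-Nd3 had a ratio of 0.578 (0.521 to 0.640), mt-Atp8, which overlaps mt-Atp6, 0.574 (0.430 to 0.765) and mt-Nd1 0.634 (0.624 to 0.643). The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2, which are not in this list, went the other way, with ratios of 15.1 and 15.9. All 20 nuclear oxidative phosphorylation genes lay below 0, with a median of -0.30, below -0.20 to 0.15, and Ndufa4, Ndufb8 and Ndufa1 had ratios of 0.710 (0.676 to 0.746), 0.727 (0.660 to 0.800) and 0.732 (0.688 to 0.778). All 23 ribosomal protein genes also lay below 0, with a median of -0.25, inside the range of random lists at that expression level (-0.28 to 0.07). Short transcripts stood lower relative to long ones. The median difference was -0.08 in the shortest eighth of protein-coding genes and 0.20 in the longest, and Spearman's rank correlation of difference with length was 0.237 across 13642 genes, which are not independent replicates.

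**Figure D3:**
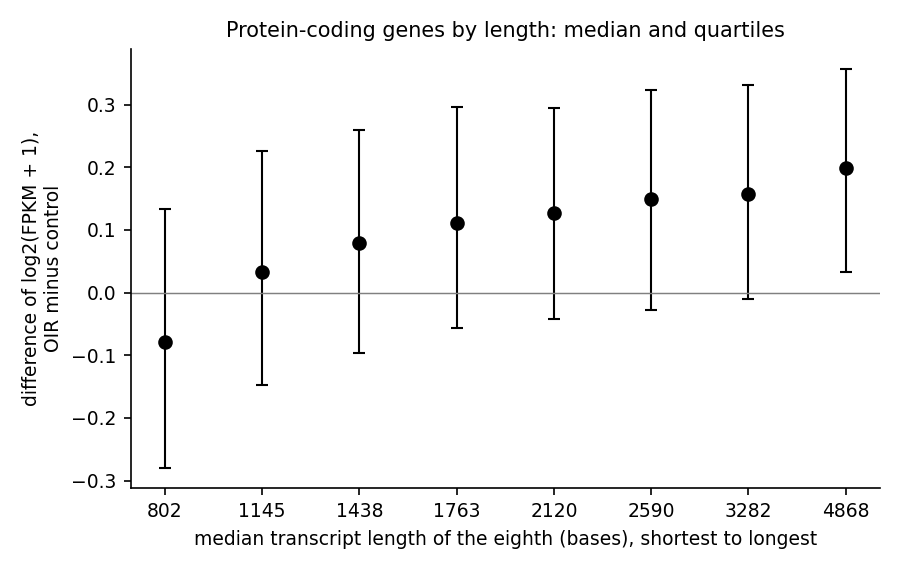
Difference of log2(FPKM + 1), OIR minus control, for protein-coding genes split into eighths by transcript length in bases. Points are medians and bars quartiles over genes of the 2 libraries. Medians run from -0.08 in the shortest eighth to 0.20 in the longest.

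Genes of some tissues outside the retina differed in read share or level between the libraries. Lens crystallins and lens fibre genes took 24.36% of reads in the control (24.34 to 24.38) and 18.51% in OIR (18.49 to 18.52), and had a median difference of -0.47 over 24 genes, 23 of them below 0. Crygn had a ratio of 0.569 (0.549 to 0.589) and Cryba2 0.626 (0.619 to 0.633). Reads of the crystallins can be shared between close copies. Corneal and conjunctival epithelium markers went the other way, with a median of 1.21 over 15 genes and 9 at least 2-fold higher. Keratin 5, Krt5 (chromosome 15, 101707070 to 101712891), had a ratio of 3.56 (3.44 to 3.69), Aldh3a1, an abundant corneal crystallin, 3.36 (3.21 to 3.52) and Dsp, the desmosomal protein desmoplakin, 7.13 (6.32 to 8.08). Melanocyte and pigment genes had a median of -0.33 over 10, with Pmel, Mlana and Tyr at 0.690 (0.670 to 0.711), 0.693 (0.632 to 0.759) and 0.757 (0.687 to 0.836). Ciliary body and iris markers had -0.22 over 14, of which 5 lay above 0, with Car3 at 0.385 (0.337 to 0.439), Wfdc1 at 0.557 (0.453 to 0.684) and Ptgds at 0.761 (0.742 to 0.782). Keratocyte and scleral fibroblast markers (0.19), extraocular muscle markers (0.20), adipocyte markers (0.07) and long noncoding RNAs (0.17) were within range, and 3 lacrimal and Harderian gland markers, with a median of 0.14, were too few to rank.

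Over all genes, 487 of the 15883 tested genes were at least 2-fold higher in OIR and 114 at least 2-fold lower. Protein-coding genes made up 276 of the higher and 22 of the lower. Few reads lay behind many of these genes: 131 of the higher and 81 of the lower had under 10 reads in both libraries, and the counting interval excluded a ratio of 1 for 352 and 37. The authors' deposited table marks 95 genes up and 7 down, of which 95 and 6 were at least 2-fold higher and lower here. Among the highest 8 genes were Edn2, Bcl3, Hsp90aa1, which encodes a chaperone and had 26798 and 947 reads, and Tnnt2, the cardiac troponin T gene, with 568 and 10. The other 4 were the rRNA genes CT010467.1, mt-Rnr1 and mt-Rnr2 and the annotated microRNA gene Gm23935, which lies within Zc3h7a, with ratios between 15.1 and 51.4. All rRNA genes took 0.153% of reads in OIR (0.151 to 0.155) and 0.00791% in the control (0.00748 to 0.00836).

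The lowest gene was Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460375 to 103483217), with 28 reads in OIR and 3203 in the control. Y-linked genes, which only males carry, were read in both libraries: Eif2s3y had 1693 and 892 reads, Kdm5d 933 and 414 and Uty 555 and 244, and the ratios of these 3 genes lay between 1.47 and 1.76. The sex-linked list, of which Xist is 1 of 5 tested members, had a median of 0.54 and a mean of -0.45, so its direction depends on which is used. The control library thus held reads of both Xist and Y-linked genes, while the OIR library held Y-linked reads with few of Xist, and the labels do not give the sex of the animals. Spc25, a kinetochore gene (chromosome 2, 69193895 to 69206194), had 273 reads in OIR and 1020 in the control, a ratio of 0.207 (0.180 to 0.237). The other 6 of the lowest 8 rested on fewer reads: Gm42808 had 21 and 75, Smim18 14 and 55, and Mir3076, Mir7220, Mir6909 and Trbd1 at most 6 in either library.

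**Figure D4:**
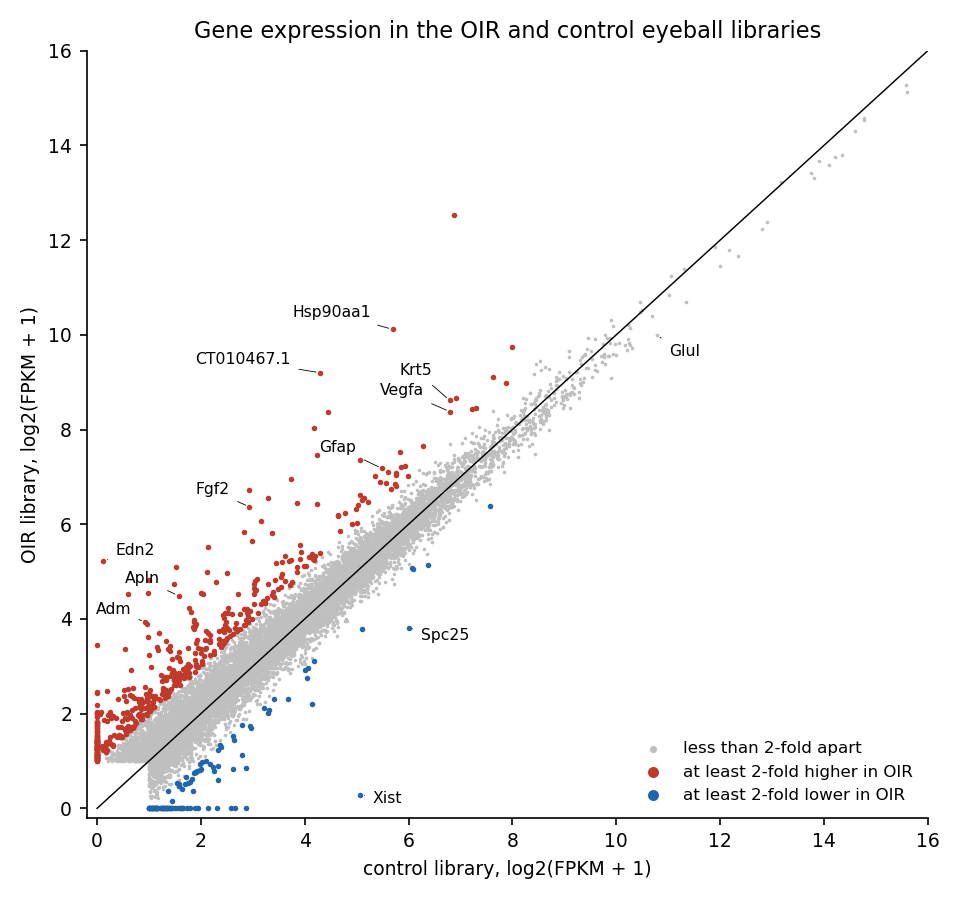
Expression of the 15883 tested genes as log2(FPKM + 1) in the control library (horizontal axis) and the OIR library (vertical axis). Each point is a gene, with 487 at least 2-fold higher in OIR in red, 114 at least 2-fold lower in blue, the rest in grey and the line marking equal values. Edn2 stands far above the line and Xist far below it.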

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

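The authors' scaling factors and centring within length bins were chosen after the data were seen. No paired analysis was possible because each group is 1 library, and for the same reason no library could be left out. The 487 higher and 114 lower genes depend on how low values are treated: there were 924 and 254 with a pseudocount of 0.1, 998 and 273 with 0.01, 251 and 27 with an FPKM filter of 5, and 276 and 22 among protein-coding genes alone, where fewer genes enter. Thresholds of 1.5-fold and 4-fold gave 1447 and 409, and 55 and 8. Rescaling to TPM gave 734 and 147, and without lens, muscle, erythrocyte and mitochondrial genes 904 and 330; the cause was not tested. CPM gave 451 and 30, which moves the split towards higher genes. At these depths the 81 lower and 131 higher genes with under 10 reads in both libraries fall under a CPM of 1, the filter then used. The rest of the change was not traced. Centring on the median, by the authors' factors and within length bins gave 374 and 144, 377 and 139, and 384 and 135. TPM put the median tested gene at 0.21 on the log2 scale and the authors' factors at -0.01, against 0.11. Between 28 and 34 lists lay outside their random range, against 31. Calls were lost for pericyte, Müller glia and visual cycle lists with the mean, and for horizontal, amacrine and interferon lists with the FPKM filter of 5. The sex-linked list reversed to -0.45 with the mean, because Xist alone lies far below its other members. All 49 named genes at least 2-fold apart kept their direction under every setting that kept them, but this could hardly come out otherwise. A pseudocount cannot turn a sign, and rescaling or centring shifted the median tested gene by far less than 1. Depth limits the 131 higher and 81 lower genes with under 10 reads in both libraries.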

Other observations

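The gene families below and the tests of explanations were chosen after the result was seen, with the exception of the search for sequence shared with rRNA, which was fixed before it was run; the genes named here that are not in the report were chosen after their values were seen.

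Some gene families are given as values only, since they were picked for a high median among 719 symbol stems and overlap the fixed lists in what they hold. The 18 tested genes of the mouse histocompatibility complex with symbols beginning H2- had a median difference of 0.72 on the log2 scale, and 14 of them lay above 0. This is not separate from the antigen presentation list, which holds 5 of them. They include H2-Q7 at 9.54 FPKM in OIR and 1.22 in the control and H2-K1 at 49.4 and 28.8, although close copies in this complex can share reads. The 23 symbols beginning Itg, mostly integrins that bind cells to matrix, had a median of 0.54, and 20 lay above 0, with Itga4 at 35.6 and 10.8 FPKM and Itgb4 at 6.25 and 1.71. The 5 mucin genes had a median of 0.91, with Muc4 at 30.1 and 4.64 FPKM and Muc2 at 13.8 and 0.940. Mucins and Itgb4 are also genes of surface epithelium, and the corneal and conjunctival epithelium list stood higher beside them, with a median of 1.21 and 9 of 15 genes at least 2-fold higher.

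The lower level of oxidative phosphorylation genes was weighed against the trend with transcript length, since these transcripts are short. After centring within 20 length bins the nuclear list kept a median of -0.28, against -0.30 before, and lay at percentile 0.22 of its random lists, so the length trend is not the whole cause. An effect of the model, different amounts of tissue in the samples and sex stay open and untested. Each group is 1 library, and RNA of a whole eyeball mixes the amount of a tissue with the expression in it. The Xist reads (3203 in the control and 28 in OIR) beside Y-linked reads in both are consistent with animals of both sexes in the control and males in OIR, which the labels do not give.

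The higher level of corneal and conjunctival epithelium genes was set against the smaller share of lens reads in OIR. That smaller share raises every other gene alike by 0.11 on the log2 scale, while the lower quartile of the epithelium list stood at 0.57 and its median at 1.21, and rod and pigment epithelium lists stood near 0. More surface epithelium in the OIR sample stays open: Krt12, the keratin of corneal epithelium, had a ratio of 2.48 (95% counting interval 2.35 to 2.62). Krt13, Krt4 and Krt15 had ratios close to it, at 2.58, 2.59 and 2.63, while Krt19 stood at 1.54, Krt14 at 2.05, Krt5 at 3.56 and Dsp at 7.13, and differences over the list ran from -0.05 to 2.49. More tissue cannot be told apart from higher expression in the same tissue, an effect of the model on the ocular surface included. RNA of a whole eyeball mixes the amount of a tissue with the expression in it. Each group is also 1 library, so neither can be assigned to the model.

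All 8 tested genes with symbols beginning Rrp, which act in ribosomal RNA processing, were at least 2-fold higher in OIR, with differences from 1.28 to 3.27 and a median of 2.05, the highest of 719 symbol stems of 3 characters with at least 5 tested genes. Rrp1 had 3818 reads in OIR and 278 in the control, and Rrp12 409 and 29, and Rpl12 and Lars2 stood out too, with 4112 and 323 and with 8282 and 406 reads. Ribosome production in general does not account for this: the other 140 genes of the rRNA processing term in the authors' deposited table had a median of 0.021 and an upper quartile of 0.16, and the median of 63 genes beginning Rpl was -0.26. Nor does sequence shared with the annotated rRNA genes: 0 of the 8 Rrp genes shared a 31-base word with 357 annotated rRNA transcripts. Counts and FPKM gave the same length in both libraries for 8 of the 8, as for all 22320 genes read in both. An edit of a count or an FPKM value alone would break this, but an edit of both together would pass the check. Such a joint edit remains open, as do a difference in library making that also left more rRNA in the OIR library and regulation in the model. Similarity to rRNA sequence that is not in the annotation is open too. None of these was tested.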
